A study of Mus musculus with 20 samples.

How the data were processed

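Total RNA from the left lateral liver lobe of 20 male mice aged 8 weeks was sequenced as paired-end fragments. The mice carried a floxed Hsd17b12 gene, 10 with Cre recombinase under the albumin promoter (KO) and 10 without Cre (WT). Genotype was taken from the sample labels, and the labels name no litter, batch or date. No paired analysis was possible because the labels give no litter or other pairing of KO with WT mice.

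The authors deposited raw fragment counts per Entrez gene, whole numbers whose sum per mouse equals the assigned fragments of the deposited fragment statistics. Multi-mapping fragments were counted by the authors and not set aside, and genes with a count of 0 in all mice are absent. The deposited file names give Rsubread with RefSeq annotation of mm10 for alignment and counting and ROTS for the test, while the submitters' processing notes name HISAT2 2.0.5 and DESeq2. The strand setting is not given in the sources used here. The authors also deposited a normalized signal, in which each count is divided by 1 factor per mouse. That signal equalled the CPM over the TMM effective library size with a largest relative deviation of 5.11e-15. The deposited RPKM values are that signal per kilobase of gene length, with a largest relative deviation of 8.77e-15. The deposited ROTS table gives a log2 fold change of KO relative to WT, and per the file headers a p-value and a false discovery rate (FDR) per gene. The deposited gene ontology tables give the number of annotated genes and an FDR p-value per term, and their tool, gene input and background are not stated. All sample columns of the deposited value tables were matched to a mouse, and 16 columns of the fragment statistics tables were not used here.

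The comparison of KO with WT used edgeR 4.0.16 in R 4.3.3 on the raw counts. Of 20914 genes, 13670 passed filterByExpr (minimum count 10, minimum total count 15), and the genes left out held 0.0858% of fragments. No symbol is given for 620 genes. Libraries were scaled by TMM factors, dispersions were estimated with robust settings, and a quasi-likelihood F test gave p-values adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. CPM values are TMM-scaled, and log2 CPM values have a prior count of 2. SE is that of the fitted log2 fold change. The lowest and highest assigned totals were 16693195 and 29124124 fragments per mouse. With 10 mice per genotype the test was also run on simulated data with 50 changed genes per fold: it called 30 at 1.5-fold, 44 at 2-fold and all 50 at 4-fold and 8-fold. In that simulation 8 of 182 calls were of unchanged genes. It left 13470 of 13670 genes unchanged and lacked the composition difference between the genotypes, while 8086 genes were called in the data. These rates may therefore not carry over to the data.

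The choice of samples, the test, the rule for named genes, 40 gene lists and a first set of alternatives were made before the data were examined. Named genes were Hsd17b12, the 10 largest rises and 10 largest falls, and up to 4 members of each list with the smallest adjusted p; some members that met this rule are not reported here. The rises and falls had an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the genotypes, and predicted genes and pseudogenes were left out. Coordinates are those of the deposited annotation, and known coding neighbours whose exons overlap a gene printed by name are given beside its first mention. Each list with at least 3 tested members, 39 of 40, was tested by camera in limma 3.58.1 on voom values with an inter-gene correlation preset at 0.01, two-sided, with adjustment over the lists. Camera called 13 lists up and 11 down, and 0 of these 24 calls held with an estimated correlation. All 24 passed with fry, which tests a list by itself and not against other genes. In 11 of the 24 called lists the means of single mice in log2 CPM did not overlap between the genotypes. For all 39 lists the median, the mean and the camera direction had the same sign. The lists cover 618 genes, of which 611 are in the table and 543 were tested.

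Measures of the libraries, the first principal component of the 1000 most variable genes and Hsd17b12 were compared by two-sided permutation tests with 100000 resamples, adjusted over 16 library measures. Relations between Hsd17b12 and 6 list means were computed within each genotype by Pearson's r and Spearman's rho with permutation p-values adjusted over 12 relations. Alternatives planned in advance were DESeq2 size factors and upper-quartile factors, no filter and a stricter filter (CPM of at least 1 in at least 10 mice), DESeq2 1.42.0, limma-voom with sample quality weights, limma-trend on log2 RPKM with pseudocounts of 0.1 and 1, a surrogate variable from sva 3.50.0, assigned fragments as a covariate, and leaving out each mouse. For lists they were an estimated correlation, members with a mean log2 CPM of at least 1, and fry. Added after seeing the data were scaling by library size alone, the properly paired share as a covariate, and fits to only the mice numbered 400 and above (8 per genotype) or below 400 (2 per genotype).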

Results

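Liver RNA from the left lateral lobe of male mice aged 8 weeks was sequenced in 10 mice with a hepatocyte-specific knockout (KO) of Hsd17b12 and 10 wild-type (WT) mice that carried the floxed gene without Cre. Hsd17b12 encodes a 3-ketoacyl-CoA reductase of the very-long-chain fatty acid elongation cycle. In the KO mice Cre recombinase was expressed from the albumin promoter, which is active in hepatocytes. The design addresses how loss of the enzyme in hepatocytes changes the liver transcriptome. All KO mice carried Cre and no WT mouse did, so effects of Cre and of that loss cannot be told apart. Between 16693195 and 29124124 fragments were assigned to genes per mouse, with 21395000 ± 3014060 in KO and 22845800 ± 3126010 in WT (mean ± SD, n = 10 each). The counts of 2 mice of a genotype differed by 13.7 to 277 in chi-square per degree of freedom over 90 pairs, more than sampling noise in every pair.

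Hsd17b12 RNA (Entrez gene 56348; mm10 chromosome 2, 94032697 to 94157909, 11 exon blocks) was lower in every KO mouse than in every WT mouse. Its level was 47.8 ± 2.39 CPM in KO and 152 ± 18.5 CPM in WT (SD, n = 10 each), which is 31.5% of the WT mean. The KO values spanned 44.2 to 51.3 CPM and the WT values 123 to 177 CPM. The log2 fold change was -1.66 (SE 0.0644; edgeR quasi-likelihood adjusted p = 3.85e-14; two-sided permutation test of log2 CPM p = 1e-05, the smallest that 100000 resamples can give). Counts over the whole gene include exons that the deletion may leave in the transcript and RNA of cells other than hepatocytes.

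**Figure D1:**
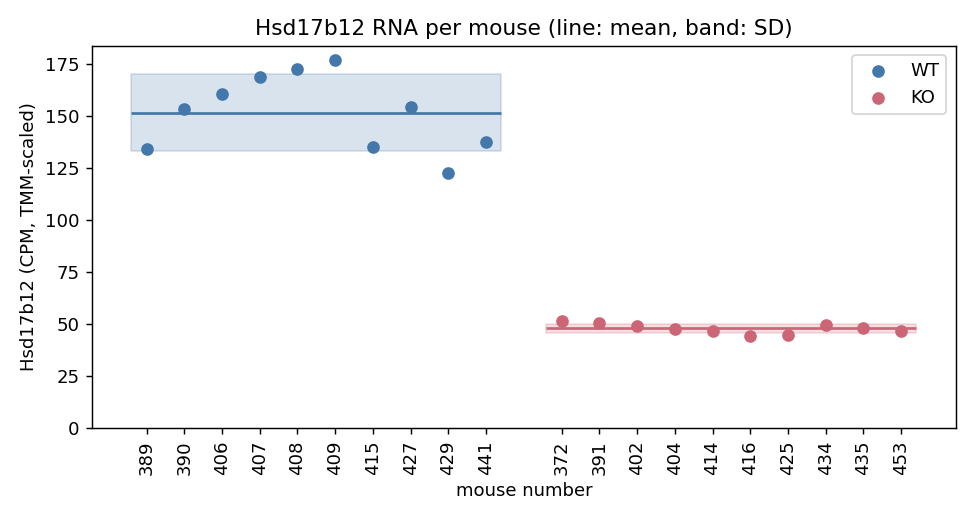
Hsd17b12 level in TMM-scaled CPM (vertical axis) in each of 20 mice, by mouse number (horizontal axis), with the mean (line) and SD (band) of 10 WT and 10 KO mice. The KO mice lie between 44.2 and 51.3 CPM, below the lowest WT mouse at 123 CPM.

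Genotype was the main axis of variation. The first principal component of the 1000 most variable genes held 73.2% of the variance and separated the genotypes, with means of -36.97 ± 14.04 in KO and 36.97 ± 7.76 in WT (SD, n = 10 each; two-sided permutation p = 1e-05, the smallest possible). Mouse KO_391 lay at -4.07, between the other KO mice (-58.21 to -28.45) and the WT mice (22.49 to 45.60).

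**Figure D2:**
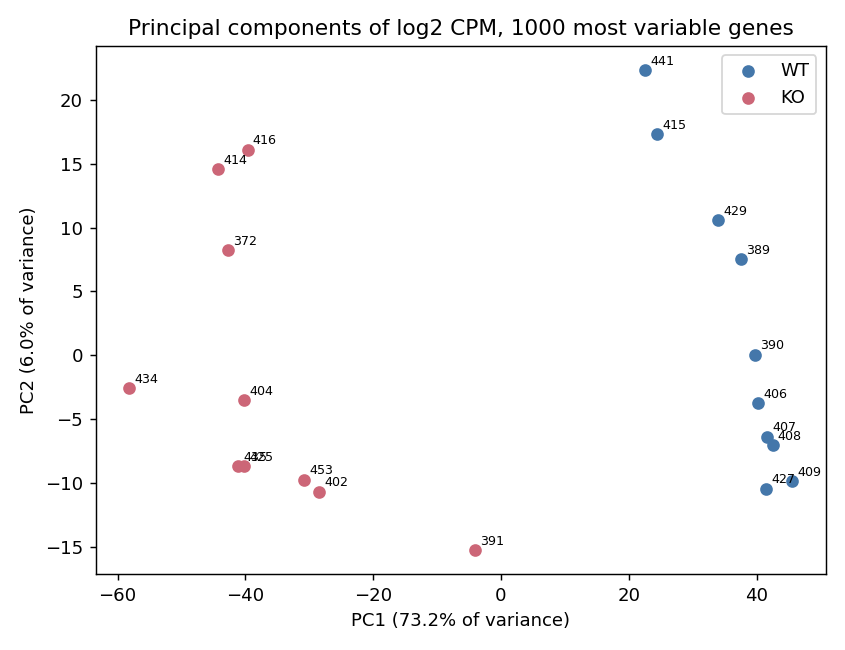
Scores of the 20 mice on the first (horizontal, 73.2% of variance) and second (vertical, 6.01% of variance) principal components of log2 CPM over the 1000 most variable genes, one point per mouse labelled by its number. KO mice lie at negative and WT mice at positive scores on the first component, and mouse KO_391 at -4.07.

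Of 13670 genes tested, 3853 were higher and 4233 lower in KO than in WT at an adjusted p under 0.05, of which 1051 were higher and 561 lower by at least 2-fold. All KO values lay above all WT values for 970 genes and below them for 884, where chance alone would give 0.00108% of genes in either direction. The split by direction depended on the scaling of the libraries. The TMM factors were 1.18 ± 0.0612 in KO and 0.852 ± 0.0609 in WT (SD, n = 10 each), and scaling by library size alone, chosen after seeing these factors, moved the median log2 fold change of all tested genes from -0.025 to 0.44. With that scaling 9355 genes were higher and 917 lower, so that 91.1% of calls were higher against 47.7% with TMM, and 4770 of the 8086 calls were shared in gene and direction. Fold changes below are with TMM factors, and lists whose median changes sign under library size scaling are named as such.

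Among genes without overlap between the genotypes, the largest rises were of genes almost silent in WT liver. Gpx2, a glutathione peroxidase of epithelia (mm10 chromosome 12, 76792335 to 76795554), rose from 0.0515 ± 0.0585 to 30.4 ± 12.7 CPM (SD, n = 10 each; log2 fold change 9.06, SE 0.45, adjusted p = 4.85e-12). Ly6d (mm10 chromosome 15, 74762056 to 74763567), a lymphocyte antigen 6 family member, rose from 0.564 ± 0.472 to 128 ± 51.7 CPM, by a log2 fold change of 7.81. Sprr1a, a cornified envelope protein, and Kif1a, a kinesin motor, rose by 8.39 and 7.90 on the log2 scale, and Ggt1, the gamma-glutamyltransferase, by 7.69. Gipc2, Lrtm2, Sdcbp2, Shc2 and Spire2 completed the 10 and rose by 7.68, 7.28, 6.81, 6.78 and 6.71. Mean WT levels of these 10 genes were 0.0515 to 0.564 CPM, so the fitted folds depend on few WT reads. The naming rule required that all 10 KO values of each gene lie above all 10 WT values.

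Among genes without overlap between the genotypes, which the naming rule required, the largest falls included steroid dehydrogenase, cytochrome P450 and protease inhibitor genes. Genes outside that rule fell as far or further. The lowest log2 fold change in the male-biased list was -7.68, and the 22 tested major urinary protein (Mup) genes had a median of -3.03. Hsd3b5, a 3-beta-hydroxysteroid dehydrogenase (mm10 chromosome 3, 98618636 to 98645534), fell from 184 ± 69.8 to 3.76 ± 6.77 CPM (SD, n = 10 each; log2 fold change -5.60, SE 0.76, adjusted p = 3.63e-06). The serine protease inhibitor Serpina1e fell from 16630 ± 3544 to 1117 ± 1032 CPM (log2 fold change -3.90, adjusted p = 1.66e-06), and Saa4, a serum amyloid A protein, from 621 ± 314 to 81.6 ± 34.7 CPM (log2 fold change -2.93). The cytochromes P450 Cyp2c37 and Cyp2c69 had log2 fold changes of -3.36 and -3.25, Hsd3b2 of -3.16, and Adgrf1, Ptgds, Derl3 and Susd4 of -3.75, -3.46, -3.22 and -3.05. Values of Serpina1e, Hsd3b2, Hsd3b5 and the Cyp2c genes are uncertain because multi-mapping fragments were counted and these genes have near-identical copies. Without mouse KO_391 the log2 fold changes of Hsd3b5 and Cyp2c37 were -6.60 and -4.04, and without mouse WT_441 that of Cyp2c69 was -2.57.

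Many genes of fatty acid synthesis and uptake were higher in KO. Among fatty acid elongation and desaturation genes, 12 of 16 tested members rose and 1 fell (12 and 1 adjusted over the list alone); adjusted p = 8.69e-04 by camera and 0.140 with an estimated correlation. Elovl7, Elovl1 and Elovl5, elongases of the first step of the cycle, rose by 4.97, 0.54 and 1.41 on the log2 scale and the desaturase Scd2 by 4.23. Exons of Elovl1 overlap those of Cdc20. In de novo lipogenesis 7 of 13 tested members rose and 1 fell (7 and 2 adjusted over the list alone), with Fasn, fatty acid synthase, at 2.22 and the acetyl-CoA carboxylases Acacb and Acaca at 1.70 and 1.24. That list had adjusted p = 0.0443 by camera and 0.453 with an estimated correlation. Fatty acid uptake and activation genes had the fatty acid transporter Cd36 (mm10 chromosome 5, 17781690 to 17888959) rise from 22.9 ± 8.69 to 243 ± 23.7 CPM (log2 fold change 3.40, SE 0.18, adjusted p = 4.57e-12). In that list 11 of 16 tested members rose and 3 fell (11 and 3 adjusted over the list alone), and Slc27a5, which activates bile acids, fell by 0.81 on the log2 scale (adjusted p = 0.0133 by camera and 0.140 with an estimated correlation). In cholesterol synthesis 14 of 24 tested members rose and 2 fell (14 and 2 adjusted over the list alone), Mvd, an enzyme of the mevalonate pathway, rising by 1.44 while Ebp had -0.67. Cholesterol synthesis had adjusted p = 0.0291 by camera and 0.606 with an estimated correlation. Under library size scaling the camera calls of lipogenesis, uptake and cholesterol synthesis ended (adjusted p = 0.446, 0.315 and 0.333), and that of elongation and desaturation did not. The folds were larger under that scaling: the medians went from 0.85 to 1.30, 0.87 to 1.33 and 0.34 to 0.80. In lipogenesis 8 rose and 0 fell there, in uptake 12 rose and 1 fell, and in cholesterol synthesis 19 rose and 1 fell. Camera sets a list against all other genes. The median of all tested genes rose as well, from -0.025 to 0.44, a shift of 0.47. Why the calls ended was not tested.

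Lipid droplet and triglyceride genes were mixed with TMM factors and mostly higher in KO under library size scaling. Of the lipid droplet proteins 9 of 17 tested members rose and 2 fell (9 and 2 adjusted over the list alone), Cidec, which enlarges droplets, rising by 3.78 on the log2 scale from 4.36 ± 1.36 to 60.2 ± 31.6 CPM, Plin3 by 0.84 and Hsd17b11 and Hsd17b13 by 0.69 and 0.62. The droplet list had adjusted p = 0.0291 by camera and 0.172 with an estimated correlation. In triglyceride synthesis 5 of 12 tested members rose and 2 fell (5 and 2 adjusted over the list alone). The acyltransferases Gpat3 and Mogat1 rose by 3.05 and 4.65, and Dgat2, an enzyme of the last step of triglyceride synthesis, had a log2 fold change of -0.98 (list adjusted p = 0.389 by camera). Sphingolipid genes had 12 rises and 5 falls among 22 tested (12 and 5 adjusted over the list alone; adjusted p = 0.0498 by camera and 0.140 with an estimated correlation). Among them were Sptlc2, a subunit of the enzyme that starts the pathway, at 1.25 and the sphingomyelinase Smpd3 at 3.74. In glycerophospholipid synthesis 8 of 16 tested members rose and 4 fell (8 and 5 adjusted over the list alone), Pcyt1a and Etnk1 rising by 0.62 and 0.73 and Pemt and Etnk2 falling by 0.73 and 1.05 (list adjusted p = 0.248 by camera). Under library size scaling the droplet and sphingolipid calls ended (adjusted p = 0.0802 and 0.0933 by camera) while their medians went from 0.44 to 0.92 and 0.42 to 0.89. For droplet proteins 14 rose and 0 fell there, for triglyceride synthesis 8 rose and 1 fell, for sphingolipid genes 18 rose and 0 fell, and for glycerophospholipid synthesis 12 rose and 2 fell.

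PPAR-alpha targets, genes induced by the fatty-acid-sensing nuclear receptor, rose as a list: 15 of 20 tested members rose and 3 fell (15 and 3 adjusted over the list alone), the median log2 fold change was 2.06, and adjusted p = 2.23e-05 by camera and 0.140 with an estimated correlation. Ehhadh, the peroxisomal bifunctional enzyme, rose from 325 ± 80.6 to 2481 ± 709.8 CPM and Acot2, a mitochondrial acyl-CoA thioesterase, by 4.05 on the log2 scale. Cyp4a10 and Ucp2 rose by 2.47 and 1.89; Acot2 and Cyp4a10 have close copies whose multi-mapping fragments were counted. The counts of the wider oxidation lists depended on the scaling, and only the median of the peroxisomal list changed sign. Of mitochondrial beta-oxidation genes 8 of 17 tested members rose and 4 fell (8 and 4 adjusted over the list alone), Acadl and Acadm rising by 0.54 and 0.35 and Etfa having -0.59 (adjusted p = 0.588 by camera). With library size scaling alone 15 rose and 0 fell, and the median moved from 0.038 to 0.51. Of peroxisomal fatty acid oxidation and biogenesis genes 4 of 25 tested members rose and 10 fell (4 and 10 adjusted over the list alone; adjusted p = 0.220 by camera), with a median of -0.11 that was 0.36 under library size scaling, where 16 rose and 3 fell. Amacr, an acyl-CoA racemase, and the peroxins Pex2 and Pex16 had -0.96, -0.49 and -0.45, with Pex16 at 0.023 under library size scaling.

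**Figure D3:**
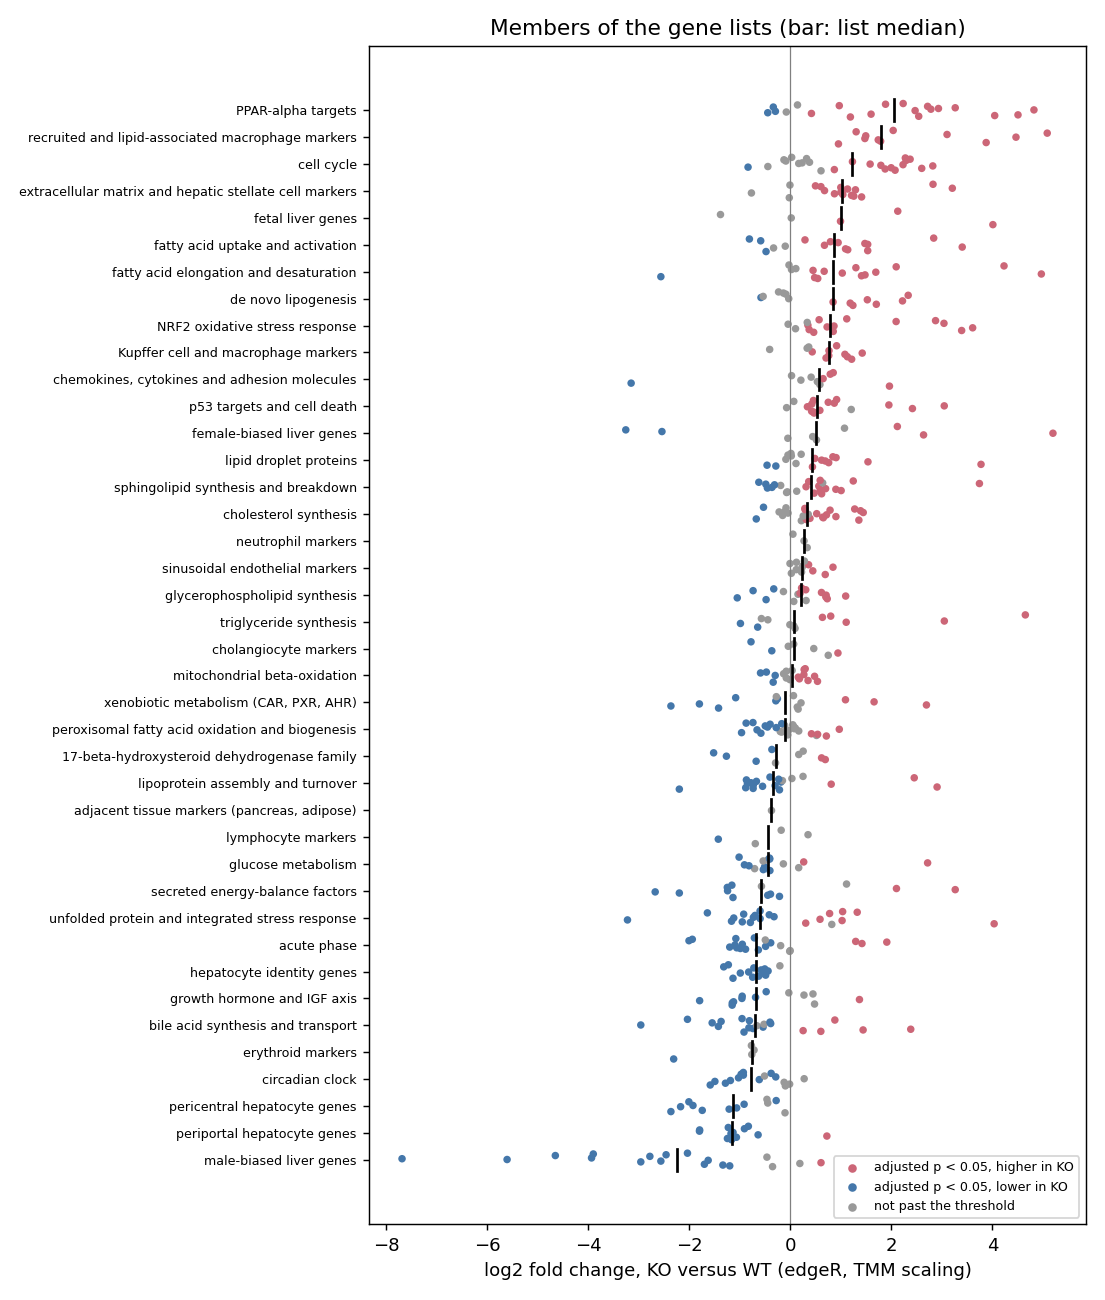
Log2 fold changes (horizontal axis, KO versus WT, TMM scaling) of every tested member of the 40 gene lists (rows), with the list median as a black bar, ordered by median. PPAR-alpha targets have the highest median at 2.06 and male-biased liver genes the lowest at -2.24.

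Lists of hepatocyte genes fell in the libraries in which the macrophage marker lists rose. Of the hepatocyte identity genes 0 of 14 tested members rose and 13 fell (0 and 14 adjusted over the list alone). They include Ttr, Ahsg, Asgr1 and Fgb with log2 fold changes of -1.22, -1.13, -0.62 and -0.99 (adjusted p = 1.03e-05 by camera and 0.140 with an estimated correlation). Under library size scaling 6 of 14 stayed lower and 1 was higher, and the list was still lower against other genes (adjusted p = 2.06e-08 by camera). Pericentral and periportal lists both fell. Among pericentral genes 0 of 12 tested members rose and 9 fell (0 and 9 adjusted over the list alone). These include Cyp1a2, Lgr5, Gulo and Rgn at -2.36, -2.17, -1.06 and -0.91 (adjusted p = 3.16e-04 by camera and 0.278 with an estimated correlation). Among periportal genes 1 of 12 tested members rose and 11 fell (1 and 11 adjusted over the list alone), including Hal, Arg1, Asl and Igfals at -1.80, -1.16, -1.24 and -1.79 (adjusted p = 0.00107 by camera and 0.330 with an estimated correlation). In the acute phase list 3 of 20 tested members rose and 13 fell (3 and 13 adjusted over the list alone), Fgg, Fga and Itih3 having -1.06, -0.88 and -1.09 (adjusted p = 0.00810 by camera and 0.355 with an estimated correlation). Counting with library size scaling, 1 rose and 8 fell among pericentral, 1 rose and 8 fell among periportal and 5 rose and 8 fell among acute phase genes.

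In bile acid synthesis and transport 5 of 20 tested members rose and 13 fell (5 and 14 adjusted over the list alone). The uptake carrier Slc10a1, the hydroxylase Cyp2c70 and the conjugating enzyme Baat had log2 fold changes of -1.37, -1.42 and -0.82, while the basolateral exporter Abcc3 rose by 1.44 (adjusted p = 0.0166 by camera and 0.355 with an estimated correlation). Of the bile acid genes 5 rose and 9 fell under library size scaling. Of glucose metabolism genes 2 of 15 tested members rose and 8 fell (2 and 9 adjusted over the list alone); Slc37a4, Fbp1 and Gckr had -1.01, -0.53 and -0.51 (adjusted p = 0.0443 by camera and 0.355 with an estimated correlation). The list median of -0.45 became 0.0061 under library size scaling, where 4 rose and 1 fell. For lipoprotein genes 3 of 20 tested members rose and 14 fell (3 and 14 adjusted over the list alone), the phospholipid transfer protein Pltp rising by 2.45 and Lcat, Apoh and Apoc4 having -0.87, -0.67 and -0.77 (adjusted p = 0.0186 by camera and 0.140 with an estimated correlation). Exons of Pltp overlap those of Ctsa. Of the lipoprotein genes 10 rose and 8 fell under library size scaling. The lipoprotein median of -0.35 became 0.11 under library size scaling. For xenobiotic metabolism 3 of 14 tested members rose and 6 fell (3 and 6 adjusted over the list alone), Cyp3a11 rising by 1.66 while Cyp2c29 and Ces2a had -1.80 and -1.42. The list had adjusted p = 0.391 by camera. Cyp2c29, Cyp2c70 and Cyp3a11 have close copies whose multi-mapping fragments were counted. The xenobiotic median was -0.094 and 0.37 under library size scaling, where 7 rose and 4 fell. In the 17-beta-hydroxysteroid dehydrogenase family, Hsd17b12 aside, 2 of 9 tested members rose and 4 fell (2 and 4 adjusted over the list alone), Hsd17b2 and Hsd17b6 having -1.26 and -1.52 (adjusted p = 0.608 by camera). The family had a median of -0.29 that was 0.16 under library size scaling, where 4 rose and 2 fell.

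Most male-biased liver genes were lower in KO: 1 of 18 tested members rose and 14 fell (1 and 15 adjusted over the list alone), with a median log2 fold change of -2.24 (adjusted p = 4.17e-05 by camera and 0.355 with an estimated correlation). The list means of the genotypes overlapped: mouse KO_391 had a mean log2 CPM of 8.53 (other 9 KO mice 5.06 to 7.15), above mouse WT_441 at 7.96. Gstp1, a glutathione transferase, fell from 1161 ± 268 to 377 ± 111 CPM, and Cyp2u1 and C8b had -1.70 and -1.20. Gstp1 and the Cyp2b, Cyp2c and Cyp3a genes have close copies whose multi-mapping fragments were counted. Female-biased genes went both ways. Cyp2b9 and Cyp3a44 rose by 5.20 and 2.12 and Cyp2c40 had -2.54, and without mouse KO_434 Cyp2b9 was at 4.61. Of the female-biased genes 3 of 9 tested members rose and 2 fell (3 and 2 adjusted over the list alone), and 11 members were below the filter (adjusted p = 0.588 by camera). In the growth hormone and IGF axis 1 of 13 tested members rose and 8 fell (1 and 8 adjusted over the list alone). Igf1, the circulating growth factor (mm10 chromosome 10, 87859056 to 87937047), fell from 643 ± 65.9 to 296 ± 49.8 CPM (log2 fold change -1.12, SE 0.093, adjusted p = 1.82e-09), its carrier Igfals had -1.79 and the receptor Ghr -1.15 (adjusted p = 0.0116 by camera and 0.140 with an estimated correlation). Among secreted energy-balance factors 2 of 13 tested members rose and 9 fell (3 and 9 adjusted over the list alone), Fetub, Enho, whose exons overlap those of Dnaic1, and Inhbc having -1.24, -2.67 and -1.24 (adjusted p = 0.0259 by camera and 0.140 with an estimated correlation). With library size scaling 2 rose and 6 fell in the growth hormone and IGF axis and 4 rose and 6 fell among the secreted factors. Circadian clock genes had 0 rises and 11 falls among 16 tested (0 and 11 adjusted over the list alone). Hlf, Cry1, Nr1d1 and Tef had -1.18, -1.28, -1.02 and -0.93 (list adjusted p = 0.0190 by camera and 0.140 with an estimated correlation). Of the clock genes 2 rose and 5 fell under library size scaling, and the clock median moved from -0.77 to -0.30.

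Stress response genes changed in both directions. In the unfolded protein and integrated stress response list 7 of 22 tested members rose and 14 fell (7 and 14 adjusted over the list alone). The genes Pdia6, whose exons overlap those of Atp6v1c2, Sdf2l1 and Derl3, which act in the endoplasmic reticulum, had -0.92, -1.64 and -3.22, while Sesn2, a target of the integrated stress response, rose by 1.33 (adjusted p = 0.124 by camera). In that list 8 rose and 7 fell under library size scaling. Targets of NRF2, the oxidative stress regulator, had 13 rises and 0 falls among 16 (13 and 0 adjusted over the list alone; adjusted p = 2.23e-05 by camera and 0.166 with an estimated correlation). Srxn1 rose from 31.5 ± 3.92 to 231 ± 67.9 CPM, and Gstm3, Cbr3 and Ugdh rose by 3.04, 3.39 and 1.12 on the log2 scale; Gstm3 has close copies whose multi-mapping fragments were counted. Of p53 targets and cell death genes 13 of 16 tested members rose and 0 fell (14 and 0 adjusted over the list alone), Mlkl, the effector of necroptosis, at 3.05 and Phlda3, Zmat3 and Ccng1 at 1.95, 0.92 and 0.59 (adjusted p = 2.22e-04 by camera and 0.140 with an estimated correlation). Cell cycle genes had 13 rises and 1 fall among 23 (13 and 1 adjusted over the list alone; adjusted p = 0.0192 by camera and 0.606 with an estimated correlation), with Ccnd1, Ccnb2, Mcm2 and Aurkb at 2.00, 2.60, 1.58 and 2.08. Under library size scaling the cell cycle call ended (adjusted p = 0.689 by camera), although 21 rose and 0 fell and the median went from 1.23 to 1.70. For fetal liver genes 3 of 5 tested members rose and 0 fell (3 and 0 adjusted over the list alone), Afp, alpha-fetoprotein, rising from 1.62 ± 0.605 to 26.0 ± 13.1 CPM and Igf2bp3 and Cd24a by 2.13 and 1.00 (adjusted p = 0.0614 by camera).

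Most markers of macrophages and matrix-producing cells were higher in KO. All 11 tested markers of recruited and lipid-associated macrophages rose (11 adjusted over the list alone). Their median was 1.79 (adjusted p = 2e-04 by camera and 0.253 with an estimated correlation). Cd63 rose from 3.01 ± 0.877 to 44.7 ± 17.9 CPM, and Mmp12, Gpnmb and Cd9 by 5.09, 4.47 and 1.79. Of Kupffer cell and macrophage markers 9 of 12 tested members rose and 0 fell (11 and 0 adjusted over the list alone), C1qb, Cd68, Cd5l and Vsig4 at 1.13, 1.42, 1.08 and 0.92 (adjusted p = 0.00108 by camera and 0.355 with an estimated correlation). In the list of extracellular matrix and hepatic stellate cell markers 15 of 18 tested members rose and 0 fell (15 and 0 adjusted over the list alone), Col4a1, Col1a2, Loxl2 and Mmp13 at 1.04, 1.26, 1.29 and 3.21 (adjusted p = 2.82e-04 by camera and 0.355 with an estimated correlation). Under library size scaling these 3 camera calls ended (adjusted p = 0.0610, 0.0539 and 0.0851), while the medians went from 1.79 to 2.25, 0.77 to 1.23 and 1.02 to 1.47. In the same order 11, 11 and 16 members rose there and none fell. Chemokine, cytokine and adhesion genes had 4 rises and 1 fall among 10 (4 and 1 adjusted over the list alone). The list has Ccl2, Tgfb1 and Icam1 rising by 1.96, 0.79 and 0.65 and Cxcl1 having -3.15, or -2.005 without mouse WT_429 (adjusted p = 0.168 by camera).

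Markers of other cell types were tested in the same way. Of sinusoidal endothelial markers 4 of 12 tested members rose and 0 fell (4 and 0 adjusted over the list alone), Cdh5, Fcgr2b, Pecam1 and Lyve1 at 0.69, 0.45, 0.36 and 0.85 (adjusted p = 0.0668 by camera). Of the endothelial markers 12 rose and 0 fell under library size scaling, with a median of 0.69 against 0.24 with TMM. For cholangiocyte markers 1 of 7 tested members rose and 2 fell (1 and 2 adjusted over the list alone), Epcam at 0.94 and Sox9 at -0.78 (adjusted p = 0.784 by camera). Of these markers 4 rose and 0 fell under library size scaling. Only 4 of 15 lymphocyte markers passed the filter, of which Cd4 fell by 1.42 on the log2 scale (list adjusted p = 0.540 by camera, median -0.43, or 0.013 under library size scaling). Among 3 tested neutrophil markers none passed the threshold, Csf3r having 0.34 with adjusted p = 0.116, and at 0.42 without mouse WT_441 it passed (list adjusted p = 0.649 by camera). Alas2, the erythroid-type 5-aminolevulinate synthase, fell from 155 ± 18.1 to 31.4 ± 11.3 CPM as the single change among 4 erythroid markers (list adjusted p = 0.259 by camera). Of 12 pancreas and adipose markers 1, Cela2a, was tested, at -0.38 with adjusted p = 0.189; its exons overlap those of Casp9.

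**Figure D4:**
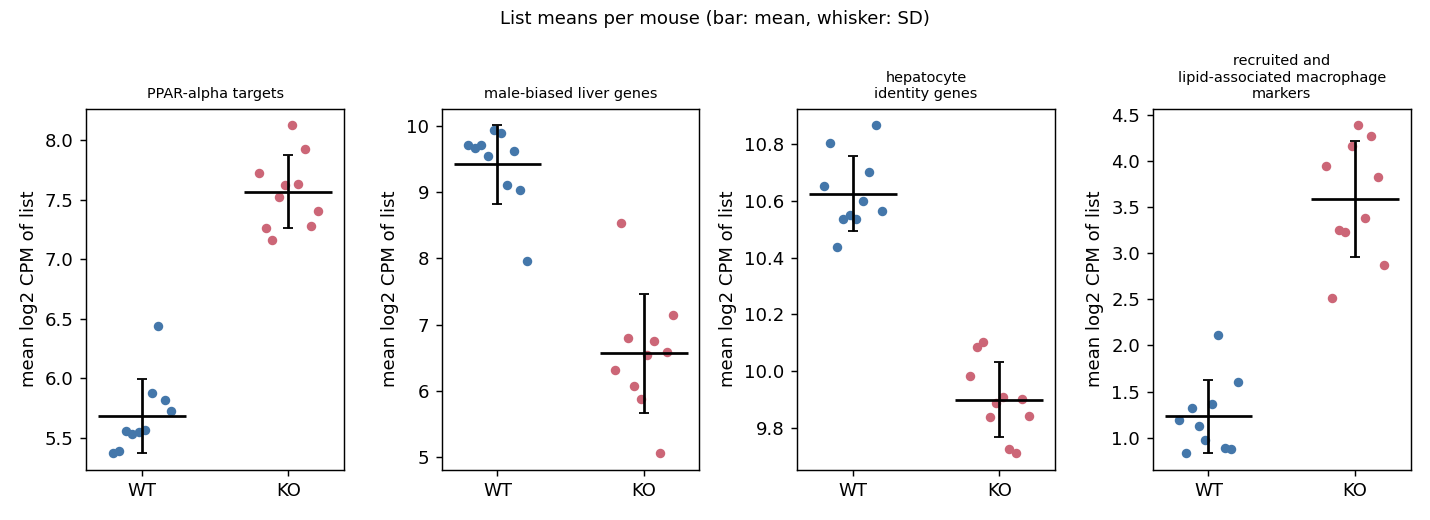
Mean log2 CPM (vertical axes) of the tested members of 4 gene lists in each of 10 WT and 10 KO mice, with the mean (bar) and SD (whisker) per genotype. The KO mean is 7.57 against 5.68 for PPAR-alpha targets and 6.57 against 9.42 for male-biased liver genes.

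The libraries of the genotypes differed in composition. The 22 major urinary protein (Mup) genes, a family secreted by male liver, took 2.14 ± 2.03% of assigned fragments in KO and 10.2 ± 5.04% in WT (SD, n = 10 each; two-sided permutation p = 4.2e-04, adjusted p = 0.00144 over 16 measures). The shares overlapped: mouse WT_441 had 2.26%, below mouse KO_391 at 7.63%, mouse KO_453 at 2.40% and mouse KO_402 at 2.34%, and mouse WT_415 and mouse WT_429, at 4.44% and 4.56%, were also below mouse KO_391. Multi-mapping fragments made up 3.32 ± 1.89% in KO and 9.68 ± 3.71% in WT (permutation adjusted p = 0.00144), and fragments falling ambiguously on several genes 3.85 ± 0.862% and 6.18 ± 1.65% (permutation adjusted p = 0.00304). The 2 mitochondrial ribosomal RNA genes in the table took 0.0865 ± 0.0153% in KO and 0.135 ± 0.0264% in WT (permutation adjusted p = 8e-04). Singletons made up 2.88 ± 0.233% in KO and 3.88 ± 0.402% in WT (permutation adjusted p = 8e-05). The assigned share was 84.8 ± 1.10% and 82.7 ± 1.72% (permutation adjusted p = 0.00774), and the mapped share 99.4 ± 0.0228% and 99.3 ± 0.0454% (permutation adjusted p = 0.00200). A mean of 17394 ± 332 genes were detected in KO and 16946 ± 448 in WT (permutation adjusted p = 0.0402). Haemoglobin genes did not differ detectably, at 0.0122 ± 0.00556% and 0.0148 ± 0.0128% (permutation adjusted p = 0.565), nor did the share of properly paired fragments, at 75.7 ± 3.34% and 74.4 ± 2.69% (permutation adjusted p = 0.410).

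Within a genotype, the Hsd17b12 level was compared with the mean of 6 lists, giving 12 relations. Among WT mice Hsd17b12 was inversely related to female-biased liver genes (n = 10, r = -0.77, permutation p = 0.00655, adjusted p = 0.0786; rho = -0.84, permutation p = 0.00365, adjusted p = 0.0438). Without the 2 mice farthest from the median Hsd17b12 level r was -0.81 (exact permutation p = 0.00960, adjusted p = 0.115). Only the rank correlation passed the adjusted threshold, and none of the other 11 relations passed it by either measure. In KO mice r lay between -0.38 for PPAR-alpha targets and 0.090 for male-biased liver genes.

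In the authors' deposited table, a ROTS test, 5247 of 12820 genes passed a false discovery rate of 0.05, with 2829 higher and 2418 lower in KO. Of the 12792 genes tested in both, 5098 passed in both and all 5098 had the same sign. A further 121 passed in the authors' table alone and 2741 in the edgeR test alone. The authors' deposited table gives Hsd17b12 a log2 fold change of -1.63. The authors' deposited enrichment tables led with amino acid metabolism (false discovery rate 7.71e-11), collagen-containing matrix (2.68e-11) and monooxygenase activity (2.07e-09).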

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

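The test of retained Hsd17b12 RNA in mouse KO_391, the test of a smaller hepatocyte share, the test of hepatocyte genes against all tested genes, and scaling by library size alone were chosen after the results they examine were seen. In 422 groups of 10 values, 25 held a mouse whose gap to its nearest neighbour exceeded Dixon's critical share of the group's range, and chance flags about 1 in 20 groups. Mouse KO_391 accounted for 11 of these, mouse KO_416, mouse KO_434, mouse WT_427 and mouse WT_441 for 3 each, and mouse WT_415 and mouse WT_429 for 1 each. The flags are not independent. Those of mouse WT_427 for the pancreas and adipose list and for Cela2a, its single tested member, rest on the same values.

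Mouse KO_391 lay 47.1% of the way from the other KO mice to the WT mean on the first principal component. Retained Hsd17b12 RNA, from incomplete recombination or admixed WT RNA, would place its level at 96.6 CPM if that place gave the share of WT RNA directly. The component is built on log2 CPM, so this linear reading need not hold. The observed level was 50.6 CPM against 47.5 ± 2.33 CPM in the other 9 KO mice (SD), a distance of -19.8 SD from the implied level. It was also below the 51.3 CPM of mouse KO_372. This argues against retained RNA in that proportion, while a smaller amount was not tested. After removal of the trend on the properly paired share, 70.2% in this mouse, it still lay 2.48 SD above the highest other KO mouse, which argues against library quality by that measure as the whole cause. The labels give no group that sets this mouse apart, so no other biological explanation was tested.

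Hepatocyte identity genes were lower in KO in 13 of 14 tested members with TMM factors. With library size scaling alone 6 of 14 stayed lower and 1 was higher, but that scaling moves all genes alike, so this count decides nothing about scaling. Within each mouse the scaling factor cancels from the mean log2 count of the list minus the median of all tested genes. This difference was 6.05 ± 0.14 in KO and 6.81 ± 0.13 in WT (SD, n = 10 each; permutation p = 1e-05). The list thus fell against the median gene under any scaling. Because no scaling factor can enter this difference, it is not a test of scaling. How far the level itself fell stays open, since no spike-in fixes the scale. A smaller share of hepatocytes would raise the markers of every other cell type alike. The median log2 fold changes of Kupffer cell and sinusoidal endothelial markers were 0.77 and 0.24 (p = 0.00648 by permutation of the marker genes). That permutation takes marker genes and not mice as replicates, and it ignores correlation between markers of a cell type. It therefore cannot decide on even dilution, and a rise in macrophages themselves stays open. A lower output of these genes per hepatocyte after loss of Hsd17b12 also stays open and was not tested.

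Mup genes were lower in KO in 21 of 22 tested members. Assignment of multi-mapping fragments to other Mup copies would leave their sum in place, but the summed level fell from 123352 ± 65229 to 19024 ± 19938 CPM (SD, n = 10 each; permutation p = 2.6e-04). The share of assigned fragments in Mup genes, which no TMM factor enters, was also lower (permutation p = 4.2e-04). Dividing by assigned fragments is itself library size scaling, so the fall held under both scalings. This argues against the choice between these scalings as its source. Lower Mup expression after loss of Hsd17b12 in hepatocytes is a candidate explanation, found and tested on the same data. Values of single Mup genes remain uncertain because their sequences are near-identical.

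Random grouping of the mice is an unlikely source of the count of differing genes. Of 100 splits of the 20 mice into groups of 10, only 1, the real one, gave as many as 8086 genes (permutation of the labels). The highest other split gave 228. That split put 7 KO mice in 1 group. All other splits mixed KO and WT mice within their groups. The splits cannot address litter or batch, which the labels do not name.

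Among library measures, mouse KO_391 had the lowest assigned share of the KO mice at 82.1 (other 9 mice 84.2 to 86.0) percent and the lowest share of counts in the top 10 genes at 14.3 (other 9 mice 16.4 to 18.1) percent. It had the highest KO share of multi-mapping fragments at 8.46 (other 9 mice 2.09 to 4.02) percent, of ambiguous fragments at 6.26 (other 9 mice 3.38 to 3.92) percent and of Mup fragments at 7.63 (other 9 mice 0.564 to 2.40) percent.

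Among list means in log2 CPM, mouse KO_391 was lowest of the KO mice for sphingolipid genes at 4.12 (other 9 mice 4.23 to 4.36) and highest for bile acid genes at 7.44 (other 9 mice 6.51 to 6.91). Mouse WT_427 was highest of the WT mice for PPAR-alpha targets at 6.44 (other 9 mice 5.37 to 5.87). Mouse WT_441 was lowest for male-biased liver genes at 7.96 (other 9 mice 9.04 to 9.94). Mouse KO_416 was highest for secreted energy-balance factors at 6.10 (other 9 mice 5.34 to 5.61). For the pancreas and adipose list, whose single tested member is Cela2a, mouse WT_427 was lowest at -1.18 (other 9 mice 0.092 to 0.79).

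Among named genes in log2 CPM, mouse KO_391 was lowest of the KO mice for Gpx2 at 2.88 (other 9 mice 4.23 to 5.58), Ly6d at 5.35 (other 9 mice 6.70 to 7.89), Elovl7 at 0.49 (other 9 mice 2.63 to 4.64) and Cbr3 at 0.27 (other 9 mice 1.95 to 3.57). Mouse KO_416 was lowest for Acacb at 7.20 (other 9 mice 7.76 to 8.18) and Tm7sf2, whose exons overlap those of Vps51, at 5.81 (other 9 mice 6.41 to 6.90). Mouse KO_434 was lowest for Adgrf1 at -3.48 (other 9 mice -1.01 to 1.35) and Alas2 at 3.35 (other 9 mice 4.66 to 5.77) and highest for Sesn2 at 4.08 (other 9 mice 3.50 to 3.75). Mouse WT_441 was highest of the WT mice for Cyp2c69 at 6.21 (other 9 mice 2.68 to 3.95) and Cyp2c40 at 7.57 (other 9 mice 5.13 to 6.10). Mouse WT_415 was highest for Scd2 at 3.28 (other 9 mice 1.20 to 2.30), and mouse WT_429 for Fga at 13.16 (other 9 mice 12.26 to 12.73).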

How the results depend on the processing

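Scaling by library size alone, the properly paired share as a covariate, and the fits to mice numbered 400 and above or below 400 were chosen after seeing the data. Hsd17b12 stayed lower in KO past the threshold in every alternative run, with a log2 fold change of -1.70 to -1.62 when each mouse was left out and -1.19 under library size scaling. Leaving out each mouse gave 3762 to 4180 genes higher and 3704 to 4289 lower, with 1042 to 1202 and 514 to 613 by at least 2-fold. DESeq2 size factors, upper-quartile factors, both filters, DESeq2, limma-voom, limma-trend, the surrogate variable and both covariates kept at least 93.7% of the calls in gene and direction. Without a filter 994 genes were lower by at least 2-fold, and with limma-trend on log2 RPKM and a pseudocount of 1, which shrinks folds of weakly expressed genes, 451 were higher and 346 lower by at least 2-fold. In the alternatives other than library size scaling and the mice numbered below 400, the named genes with a value kept their direction and their side of the threshold, except Csf3r, which passed with sample quality weights at 0.47 and without mouse WT_441 at 0.42. On simulated data of this depth and size, with 13470 of 13670 genes unchanged, 30 of 50 genes changed 1.5-fold were called. Small changes can thus be missed, though the rate may differ in the data, where many more genes were called. No paired analysis was possible because the labels give no litter or other pairing of KO with WT mice.

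Library size scaling gave 9355 genes higher and 917 lower, with 2387 and 245 by at least 2-fold, because it shifts the median log2 fold change of all tested genes by 0.47. The log2 fold changes of Etfb, Pex16 and Cela2a then turned to 0.0067, 0.023 and 0.078, and 9 of 154 named genes no longer passed, while Csf3r newly passed at 0.79. Mice numbered 400 and above gave 3865 genes higher and 3655 lower. Mice numbered below 400, 2 per genotype, gave 700 higher and 505 lower, 396 and 201 by at least 2-fold. This smaller fit had KO_372 and the flagged KO_391 in KO, and 92 named genes no longer passed. Of these Cxcl1 and Sox9 were at 0.26 and 0.019. At an adjusted p under 0.01 in both, 2793 genes overlapped with the authors' deposited test. Without the 2 mice farthest from the median, r within KO turned to 0.12 for PPAR-alpha targets and 0.073 for the unfolded protein response; the cause was not tested.

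None of the 24 camera calls held with an estimated correlation, where the adjusted p was 0.140 for PPAR-alpha targets, circadian clock, fatty acid elongation and desaturation, fatty acid uptake and activation, growth hormone and IGF axis, hepatocyte identity genes, lipoprotein assembly and turnover, p53 targets and cell death, secreted energy-balance factors and sphingolipid synthesis and breakdown. It was 0.166 for NRF2 oxidative stress response, 0.172 for lipid droplet proteins, 0.253 for recruited and lipid-associated macrophage markers, and 0.278 for pericentral hepatocyte genes, 0.330 for periportal hepatocyte genes, 0.355 for Kupffer cell and macrophage markers, acute phase, bile acid synthesis and transport, extracellular matrix and hepatic stellate cell markers, glucose metabolism and male-biased liver genes, 0.453 for de novo lipogenesis, 0.606 for cell cycle and cholesterol synthesis. These settings differ in whether the correlation was preset or estimated. Which part of that change ended the calls was not tested.

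With fry, which tests a list by itself and not against other genes, 9 lists passed that camera did not call, with an adjusted p of 7.76e-05 for fetal liver genes, 5.35e-04 for glycerophospholipid synthesis, 0.00265 for erythroid markers, 0.00403 for unfolded protein and integrated stress response, 0.00510 for xenobiotic metabolism, 0.0186 for peroxisomal fatty acid oxidation and biogenesis, 0.0215 for sinusoidal endothelial markers, 0.0337 for chemokines, cytokines and adhesion molecules, 0.0376 for triglyceride synthesis. Under library size scaling 9 camera calls were lost, with an adjusted p of 0.0539 for Kupffer cell and macrophage markers, 0.0610 for recruited and lipid-associated macrophage markers, 0.0802 for lipid droplet proteins, 0.0851 for extracellular matrix and hepatic stellate cell markers, 0.0933 for sphingolipid synthesis and breakdown, 0.315 for fatty acid uptake and activation, 0.333 for cholesterol synthesis, 0.446 for de novo lipogenesis, 0.689 for cell cycle. The median log2 fold change of each of these lists was larger under that scaling, and so was that of all tested genes. Why these calls were lost was not tested. Under the same scaling 4 lists were gained, all as lower against other genes, at 3.31e-04 for unfolded protein and integrated stress response, 0.00594 for erythroid markers, 0.00696 for xenobiotic metabolism, 0.0467 for lymphocyte markers. Their medians went from -0.60 to -0.12 for the unfolded protein list, -0.76 to -0.30 for erythroid markers, -0.094 to 0.37 for xenobiotic metabolism and -0.43 to 0.013 for lymphocyte markers. For 4 lists without a call the camera direction against other genes turned from higher to lower, at 0.116 for female-biased liver genes, 0.670 for neutrophil markers, 0.689 for chemokines, cytokines and adhesion molecules and cholangiocyte markers, while their medians rose from 0.52 to 0.94 for female-biased genes, 0.27 to 0.74 for neutrophil markers, 0.56 to 1.02 for chemokines and 0.069 to 0.54 for cholangiocyte markers. With only members of higher mean count the adjusted p was 0.0765 for sphingolipid synthesis and breakdown, which was no longer called, and 0.323 for cholangiocyte markers, 0.853 for female-biased liver genes, whose camera direction against other genes turned without a call; the cause was not tested.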

Other observations

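Families of genes sharing a symbol stem, 211 in all, were formed and tested after the data were seen, and so were the genes named in the next paragraph. Most tested Psmd, Psma and Psmb genes, which encode parts of the proteasome, were higher in KO. Of regulatory-particle Psmd genes 12 of 14 rose and 1 fell, with a median log2 fold change of 0.77 (adjusted p = 1.65e-06 by camera and 0.550 with an estimated correlation), and of the core Psma and Psmb genes 7 of 8 and 7 of 10 rose (adjusted p = 0.0116 and 0.0174 by camera, 0.550 and 0.612 with an estimated correlation). Complex I genes of the respiratory chain were lower with TMM factors: 12 of 12 Ndufb, 11 of 14 Ndufa and 10 of 10 Ndufs genes fell, with medians of -0.50, -0.35 and -0.34, which were -0.031, 0.12 and 0.14 under library size scaling (adjusted p = 2.87e-05, 0.00294 and 0.00806 by camera, 0.550, 0.612 and 0.550 with an estimated correlation). Ribosomal Rpl genes had a median of -0.25 that turned to 0.23 under that scaling. Of Serpina genes, secreted protease inhibitors of the liver, 15 of 19 fell, with a median of -1.26 and -0.80 under the 2 scalings, and their close copies share multi-mapping fragments (adjusted p = 1.48e-04 by camera and 0.550 with an estimated correlation). Of Toll-like receptor genes 9 of 10 rose and of matrix metalloproteinase genes 8 of 9, with medians of 0.97 and 0.78 (adjusted p = 0.0174 and 0.0148 by camera, 0.550 and 0.550 with an estimated correlation). The lowest adjusted p of any family with an estimated correlation was 0.550.

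Some members of the fixed lists outside the naming rule were chosen after their values were seen. Fgf21 and Gdf15, hormones that liver secretes under metabolic stress, rose by 3.27 and 2.10 on the log2 scale. Atf3, Ddit3 and Trib3, transcription factors and a pseudokinase of the integrated stress response, rose by 4.04, 1.03 and 1.04, while the endoplasmic reticulum chaperone gene Hspa5 had -0.32, less than the shift of 0.47 between the scalings. Scd1 and Elovl6 rose by 2.10 and 1.48, and Elovl3, an elongase that is also on the male-biased list, had -2.56. Nqo1, a quinone reductase, rose by 2.10, and Trem2, a receptor of lipid-associated macrophages, by 2.04. Glul and Cyp2e1, pericentral enzymes, had -1.21 and -1.74. Each of these passed the adjusted threshold with TMM factors.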
